A study of Mus musculus with 32 samples.

How the data were processed

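The series holds 32 samples of mouse embryonic stem (ES) cells of strain 129. They comprise 8 CTCF ChIP-seq samples, 14 RNA-seq samples and 10 Med-Seq samples, the last a sequencing assay of methylated DNA based on LpnPI digestion. Processed files were used for the 14 RNA-seq samples and for 2 of the ChIP-seq samples. The other 6 ChIP-seq samples and the Med-Seq samples were not analysed here.

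RNA-seq libraries were made with a stranded mRNA kit and read as single-end 50 bp reads, per the labels' protocols. The authors deposited RPKM values, that is reads per kilobase of exon scaled to library size, for 24940 genes in each library. Per the file headers, they were counted over exons of RefSeq transcripts of mouse build mm10 with HOMER analyzeRepeats, with 1 transcript kept per gene. The header names no strand setting, so reads from a gene and from an overlapping antisense gene cannot be told apart. The submitters' processing notes also name HISAT2, SAMtools, deepTools, Bowtie and DESeq2, and the builds mm10 and mm9, with no versions. Of the genes, 410 had more than 1 copy in the annotation.

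The low RPKM values are whole multiples of what 1 read is worth. Reading these steps back gave 14.3 to 16.7 M reads per library, of which 12.0 to 14.1 M lay in genes. With a tolerance of 0.1 read, 99.8 to 99.9% of the values checked came out whole. These depths are estimates from the deposited values.

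A further deposited table of the authors' own comparison of control with del8 cells lists 1280 genes with a log2 fold change, a p-value and an adjusted p-value. Its 5 per-library columns match no sample of the series by name, and they were used only to read the direction of the fold change. The table states neither the test nor the sign convention. For all 1280 genes the sign of the log2 fold change was that of the del8 mean minus the control mean in these columns, so the values are del8 over control. All of its genes have an absolute log2 fold change of at least 0.5 and an adjusted p-value of at most 0.05, as the values show.

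The deposited ChIP-seq peak lists came from 1 library each. Per the file headers, peaks were called with HOMER findPeaks in factor style at a false discovery rate of 0.001. Each peak had to stand at least 4-fold over its surrounding 10000 bp, and no control library is named in the command. The ChIP-seq reads were 36 bp long, per the labels' protocols. The GC list was called from 8.09 M tags with a threshold of 9 tags per peak, and the Del8 list from 5.59 M tags with a threshold of 8 tags. Scaled to 10 M tags these thresholds were 11.1 and 14.3. The peaks were 233 and 247 bp wide, and every score in the deposited lists is 1. The peak coordinates were taken as mm10, because some peak ends pass the ends of mm9 chromosomes. Of the GC peaks, 8.8% lay within 1 kb of an annotated mm10 start site, against 3.3% after a shift by 100 kb. Coordinates are given 1-based.

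The independent unit was the cell line, with 2 GC lines and 3 d8 lines. Several samples were taken from each line, so values were averaged per line on the log2(RPKM + 1) scale before testing. A fold change on this scale understates the change of low genes. Genes entered the test with a mean of at least 1 RPKM in either genotype, which left 12468 genes. The test was limma (version 3.58.1, in R 4.3.3) with a trend in the variance, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design anticipated either counts or RPKM, and the RPKM branch applied. Genes differing between lines of a genotype were tested with limma over the 14 libraries. Those p-values measure only the spread between samples of a line, which may be technical.

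Gene lists were fixed beforehand, 21 in all, and tested with camera from limma at a preset correlation between genes of 0.01. They covered general, naive and formative pluripotency, 2-cell-like cells, germline, primitive endoderm, trophoblast, mesoderm, neuroectoderm and fibroblasts or feeder cells. The others were clustered protocadherins, Hox clusters, imprinted genes, CTCF with cohesin, DNA methylation, p53 targets, stress response, glycolysis with hypoxia, the X-inactivation centre, proliferation and ribosomal proteins. Camera with an estimated correlation and fry were alternatives.

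Genes were named by a rule. It took Ctcf, then the 12 highest and the 12 lowest log2 fold changes among genes past the threshold whose line means did not overlap between genotypes and whose higher genotype mean was at least 2 RPKM. From each list it took up to 4 members past the threshold with the largest change, or up to 2 members of the highest level, given as values, where fewer than 2 passed. Of the genes this rule selected, 2 are not reported here. For peaks it took the 5 retained and 5 lost GC peaks with the highest score. As every score is 1 and the width is fixed, the position in the list replaced the score, a change made after the files had been seen. That this order follows the strength of the peaks is an assumption, since the lists do not state it.

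Peak lists were compared with bedtools 2.31.1. A GC peak was called retained if a Del8 peak overlapped it by at least 1 bp and lost otherwise. Shares carry 95% Wilson intervals, which cover counting error only. List positions were compared with a two-sided permutation test of 100000 resamples over peaks, which describes these libraries and not the conditions. Genes with a GC peak within 5 kb of the start site were compared with Fisher's exact test. A search for the CTCF motif needs a genome sequence, which was not used here, so that planned result was not run.

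Alternatives planned before the data were examined were a pseudocount of 0.1, no expression filter, rescaling to the median ratio and the 14 libraries with the line as a random block or as independent samples. A replicate block by sample letter or number, each line and each library left out, an absolute log2 fold change of at least 1 and robust variance moderation were also planned. For peaks they were a reciprocal overlap of 50%, peak centres within 100 bp and distances of 1 kb and 50 kb. Added after the data had been seen were leaving out chromosome 11, centring each chromosome in each line, voom on the recovered reads summed per line, averaging samples d8 1A and 1B, leaving out samples GC 2C and d8 2B, and the alternatives by list position. The genes near peaks and the comparison with the authors' deposited table were also repeated under these alternatives, chosen at the same stage.

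The limma step was tested on simulated data with the real genes, in which 200 of 12468 genes changed in 5 draws. It recovered 20.6% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 95.2% of those changed by 2, with false calls at 2.5%. Camera found 20 of 20 lists shifted by 0.5 and called 2 of 20 unshifted lists. The simulated genes varied independently of each other, so these rates do not cover shifts that genes share, such as those along a chromosome. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.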

Results

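CTCF is a zinc finger protein that binds DNA and, together with cohesin, shapes chromatin loops. The ES cells studied expressed CTCF fused to green fluorescent protein (GC), or the same fusion lacking zinc finger 8 (d8 in RNA-seq, Del8 in ChIP-seq). RNA-seq covered 2 GC lines with 3 samples each and 3 d8 lines, of which lines 1 and 2 had 3 samples and line 3 had 2. Between 17385 and 18033 genes were above 0 per library, and the 10 highest genes held 3.5 to 4.5% of the reads. CTCF ChIP-seq peak lists came from 1 GC and 1 Del8 library, without replicates. The comparisons addressed how loss of zinc finger 8 bears on gene expression and on CTCF binding. All coordinates are in mm10.

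Ctcf itself (chromosome 8, 105636538 to 105682922) differed more between the GC lines than between genotypes. In GC line 1 the samples stood at 5.58, 5.96 and 6.23 RPKM, and in GC line 2 at 30.5, 30.8 and 22.9 RPKM. The d8 samples ranged from 23.2 to 37.2 RPKM, with line means of 28.5, 33 and 34.5 RPKM. The difference between genotypes did not pass the test (log2 fold change 1.21, SE 0.53, limma adjusted p = 0.19). It passed in fits over the single libraries, with the line as a random block (limma adjusted p = 0.024), with a replicate block by sample letter (0.042) or full sample number (0.033) and with 14 independent libraries (0.016), and also without GC line 2 (log2 fold change 2.24, limma adjusted p = 0.019). Without GC line 1 the log2 fold change was 0.18 (limma adjusted p = 0.47). GC line 2 stood 4.74-fold above GC line 1 (log2 difference 2.06, SE 0.13, limma adjusted p = 1.4e-06, with all 3 samples above all 3). Whole-gene RPKM does not show whether zinc finger 8 was present, so these values do not check the deletion.

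**Figure D1:**
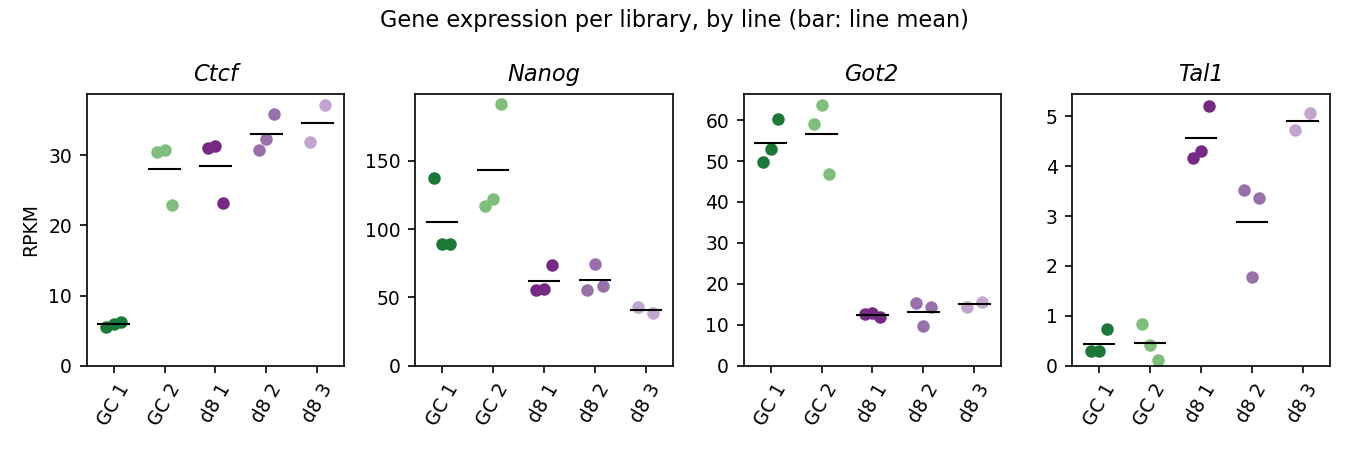
RPKM of Ctcf, Nanog, Got2 and Tal1 in each of the 14 RNA-seq libraries, with 1 point per library and a bar at the mean of each line. Ctcf lay between 5.58 and 6.23 RPKM in GC line 1 and between 22.9 and 37.2 RPKM in the other lines, while Got2 and Nanog were lower and Tal1 higher in the d8 lines.

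Between genotypes, 1092 of 12468 genes changed, 376 higher and 716 lower in d8. The genes that rose most included Tal1, a transcription factor of blood formation, Gata4, a transcription factor of primitive endoderm, and Gpx2, a glutathione peroxidase. Those that fell most included Col1a1, a collagen of connective tissue, Ocrl, an inositol phosphatase, and Got2, a mitochondrial aspartate aminotransferase. Of the changed genes 389 lay on chromosome 11, where 387 fell and 2 rose. In a principal component analysis of 12157 genes, component 1 held 39.1% of the variance and separated all GC libraries (15.6 to 25.2) from all d8 libraries (-24.1 to -6.74).

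Among the 12 highest genes, log2 fold changes lay between 1.32 and 1.80 (limma adjusted p from 0.0085 to 0.037), and none was on chromosome 11. Tal1 (chromosome 4, 115056426 to 115071755) rose from 0.449 ± 0.00943 RPKM in GC (SD, n = 2 lines) to 4.11 ± 1.08 RPKM in d8 (SD, n = 3 lines), a log2 fold change of 1.80 (SE 0.21, limma adjusted p = 0.015). Gpx2 rose from 12.7 ± 4.52 to 42.7 ± 11.4 RPKM and Gata4 from 1.51 ± 0.349 to 6.59 ± 1.74 RPKM. Nupr1, a stress-induced nuclear protein, rose from 17.5 ± 2.26 to 50 ± 5 RPKM (log2 fold change 1.44, SE 0.12, limma adjusted p = 0.0085). Tex15, which acts in the silencing of transposons in male germ cells, rose from 5.96 ± 0.395 to 16.6 ± 3.14 RPKM, Prss50, a testis protease, from 1.40 ± 0.496 to 5.56 ± 0.999 RPKM, and D1Pas1, a testis helicase, from 3.90 ± 2.04 to 12.8 ± 4.13 RPKM. Others were Nrg2, a growth factor of the epidermal growth factor family (log2 fold change 1.54), the protease inhibitor Serpina3m (1.69), the circadian repressor Bhlhe41 (1.38) and the ubiquitin ligase Trim63 (1.36).

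The 12 lowest genes had log2 fold changes from -2.61 to -1.83 (limma adjusted p from 0.0014 to 0.042), and 4 of them, Col1a1, Krt19, Scrn2 and Pttg1, lay on chromosome 11. Ocrl (chromosome X, 47912456 to 47965866) fell from 7.40 ± 0.0806 RPKM in GC to 0.604 ± 0.0861 RPKM in d8 (log2 fold change -2.39, SE 0.12, limma adjusted p = 0.0014). Got2 (chromosome 8, 95864137 to 95888365) fell from 55.4 ± 1.53 to 13.5 ± 1.32 RPKM (log2 fold change -1.96, SE 0.10, limma adjusted p = 0.0014). Other genes of mitochondrial proteins were Bola3, an iron-sulfur cluster factor, which fell from 7.95 ± 1.41 to 0.816 ± 0.116 RPKM, and the peptidase Mipep, which fell from 8.44 ± 0.0681 to 1.51 ± 0.312 RPKM. R3hcc1 fell from 14.9 ± 0.0108 to 1.96 ± 0.472 RPKM. Bak1, which promotes apoptosis, stood at 2.76 RPKM in GC line 1, 12.6 RPKM in GC line 2 and 0.312 to 0.577 RPKM in the d8 lines. The skeletal actin Acta1 (log2 fold change -2.43), the interferon-induced Gbp2 (-2.07), keratin Krt19 (-2.05), Scrn2 (-1.99) and securin Pttg1 (-1.83) completed the set.

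**Figure D2:**
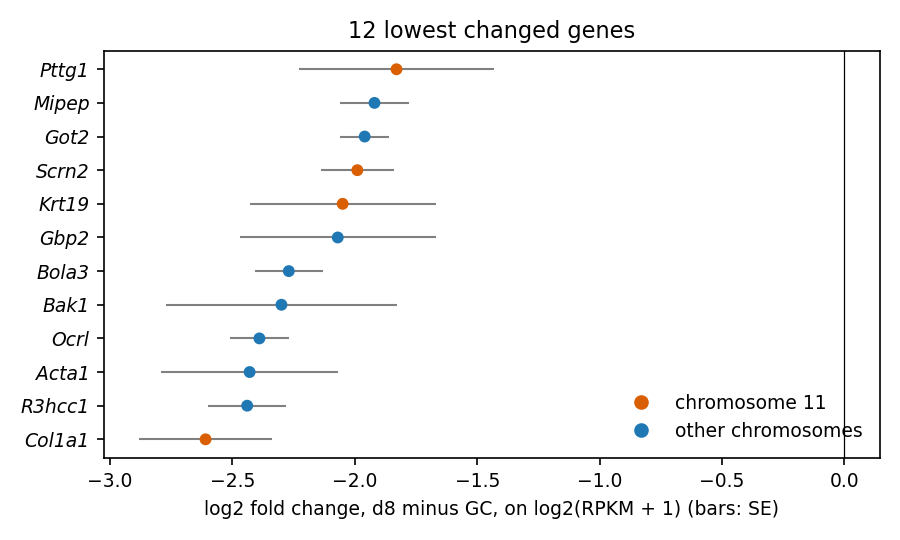
Log2 fold change, d8 minus GC, on the log2(RPKM + 1) scale for the 12 lowest changed genes, with bars of 1 standard error and chromosome 11 genes in orange. Values run from -2.61 for Col1a1 to -1.83 for Pttg1, and 4 of the 12 genes lie on chromosome 11.

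Chromosome 11 was lower in d8 along its whole length. Its 1067 tested genes had a median log2 fold change of -0.40, with 88.8% of them below 0, while the medians of the other chromosomes lay between -0.13 and 0.06. All 13 windows of 10 Mb along it had medians between -0.49 and -0.37. Chromosome 11 supplied 54.1% of the genes that fell and 8.6% of the genes tested. On the other chromosomes 374 genes rose and 329 fell. Among 595 chromosome 11 genes at 10 RPKM or more, the median ratio of GC to d8 was 1.37, with quartiles of 1.24 and 1.52. Each GC library stood above the mean of the d8 libraries on this chromosome, by 0.27 to 0.48 in the median log2 value, while single d8 libraries lay within -0.07 to 0.07. With chromosome 11 left out of the test, 188 genes rose and 180 fell. Thus 368 of the 703 genes called on the other chromosomes stayed past the threshold. The rest passed only with the chromosome 11 genes in the test, as the p-values are adjusted over all genes together. With each chromosome centred in each line 260 rose and 229 fell. Of the 58 changed genes named here, 9 lay on chromosome 11. Of the other 49, 32 stayed past the threshold with chromosome 11 left out, and the highest adjusted p from limma was 0.072. Those that missed it included Bak1, D1Pas1, Apoe, Otx2, Mael, Sycp3, Stag2, Atf4, Xist, Hoxd13, Tfap2c, S100a4, Magel2, Vegfa, Pdk1 and Rpl22l1. With each chromosome centred in each line, 37 of the 58 stayed past the threshold. Among those that did not were Krt19 (limma adjusted p = 0.056), Pttg1 (0.078) and Bak1 (0.051).

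**Figure D3:**
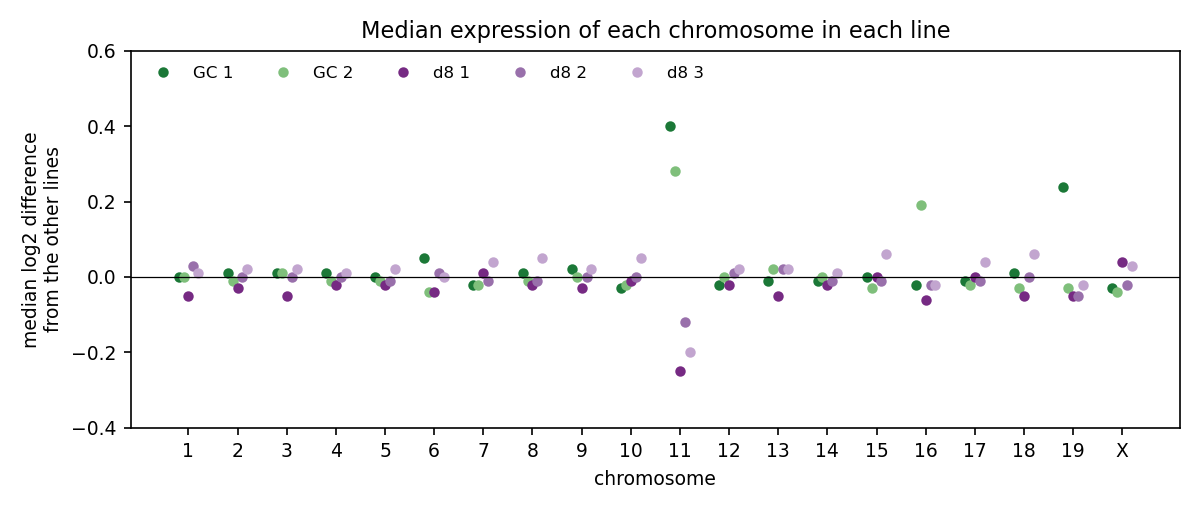
Median log2 difference of the tested genes of each chromosome in each line from the other lines, with 1 point per line. On chromosome 11 the GC lines stood at 0.40 and 0.28 and the d8 lines between -0.25 and -0.12. GC line 1 stood at 0.24 on chromosome 19 and GC line 2 at 0.19 on chromosome 16. Each line was set against the median of all other lines. For a d8 line these include the GC lines, so the points have no common baseline.

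The number of changed genes rested on each of the 5 lines. It was 27 without GC line 1, 511 without GC line 2, and 117, 579 and 30 without d8 lines 1, 2 and 3. All 1092 genes kept their direction in each of these, but they were chosen from the same 5 lines, so this is no independent support. Without GC line 1, none of the 12 highest genes passed the threshold (limma adjusted p from 0.052 to 0.13), although their log2 fold changes stayed between 1.07 for D1Pas1 and 2.04 for Gpx2, while 9 of the 12 lowest did, among them Ocrl, Got2, Bola3 and Bak1.

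Gene lists fixed beforehand moved in both directions, with 7 lists higher and 3 lower in d8 by camera, limma's list test. None of these 10 calls held with an estimated correlation between genes. The X-inactivation centre, the region that controls silencing of the X chromosome, and primitive endoderm genes stood highest, and fibroblast genes lowest. These 3 lists passed in camera with each line left out in turn.

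Of 6 genes tested in the X-inactivation centre, 4 rose and all 6 were positive, with 5 passing when adjusted over the list alone (camera adjusted p = 3.5e-04). With an estimated correlation the list had adjusted p = 0.45. Ftx, a noncoding activator of Xist, rose from 2.31 ± 0.672 to 6.50 ± 1.44 RPKM. Tsix, the antisense repressor of Xist, rose from 1.86 ± 0.255 to 5.07 ± 1.11 RPKM (log2 fold change 1.07, SE 0.18, limma adjusted p = 0.024), and Xist from 0.518 ± 0.0785 to 1.41 ± 0.315 RPKM. Because Xist and Tsix overlap on opposite strands, their values could not be separated.

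Of 13 primitive endoderm genes, 3 rose, namely Gata4, the lipid carrier Apoe and the endocytic receptor Lrp2, and 12 were positive (5 adjusted over the list alone, camera adjusted p = 0.0011). The adjusted p was 0.65 with an estimated correlation. Apoe rose from 388 ± 64.7 to 796 ± 213 RPKM and Lrp2 from 16.6 ± 1.20 to 31.9 ± 3.95 RPKM. Chromosome 11 held 1 member of this list, and without that chromosome the camera adjusted p was 4.0e-04.

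Of 11 fibroblast or feeder cell genes, 6 fell and none rose (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0018). This list had adjusted p = 0.65 with an estimated correlation. Col1a1 fell from 11.8 ± 4.91 to 0.897 ± 0.527 RPKM (log2 fold change -2.61, SE 0.27, limma adjusted p = 0.012). Col1a2 fell from 3.75 ± 1.71 to 0.237 ± 0.156 RPKM, smooth muscle actin Acta2 from 68.2 ± 21.1 to 17.3 ± 5.04 RPKM and S100a4 from 3.34 ± 1.59 to 0.882 ± 0.384 RPKM. Within the GC libraries Col1a1 and Col1a2 were highest in sample 2C, at 28.0 and 11.2 RPKM, and Acta2 and S100a4 in sample 1B, at 165 and 8.90 RPKM.

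Pluripotency genes moved unevenly. Of 15 general pluripotency genes, Tdgf1, a co-receptor of Nodal, rose from 185 ± 9.62 to 257 ± 20.6 RPKM, while Nanog, a core transcription factor, fell from 124 ± 27.1 to 55.1 ± 12.4 RPKM (log2 fold change -1.14, SE 0.21, limma adjusted p = 0.029). The list as a whole had 13 positive members and passed as higher (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.044). It had adjusted p = 0.76 with an estimated correlation, 0.9 without GC line 1, 0.16 without d8 line 1, 0.087 without d8 line 2, 0.086 without chromosome 11, 0.06 with the line as a random block and 0.062 with a replicate block by sample letter. Among 12 formative genes, Otx2 rose from 29.7 ± 1.53 to 59.6 ± 16.8 RPKM and the DNA methyltransferase Dnmt3b from 203 ± 3.78 to 300 ± 29.4 RPKM (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.03). For this list the adjusted p was 0.76 with an estimated correlation, 0.34 without GC line 2, 0.062 without d8 line 1 and 0.056 without chromosome 11. With the line as a random block and with a replicate block by sample letter or by full sample number, it was 0.15, 0.18 and 0.12 for the formative list and, in limma, 0.091, 0.13 and 0.093 for Dnmt3b. Of 15 naive pluripotency genes, Tbx3 and Gbx2 rose, with log2 fold changes of 1.06 and 0.73, and the list did not pass (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.53).

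Among 16 germline genes, Mael and Sycp3 rose, from 5.70 ± 2.16 to 15.8 ± 5.27 RPKM and from 6.94 ± 3.47 to 15 ± 0.737 RPKM (3 adjusted over the list alone, camera adjusted p = 0.029). The list had adjusted p = 0.77 with an estimated correlation, 0.49 without GC line 1 and 0.31 without d8 line 2. Of 10 mesoderm genes none changed over all genes tested, 9 were negative and 5 fell adjusted over the list alone (camera adjusted p = 0.023). It had adjusted p = 0.76 with an estimated correlation, 0.14 without GC line 1, 0.062 without d8 line 1 and 0.068 without d8 line 2. T, the primitive streak factor, stood at 42.5 RPKM in GC line 1, 5.83 RPKM in GC line 2 and 2.71 to 13.2 RPKM in the d8 lines, and Snai1 at 4.17 and 4.41 RPKM in the genotype means. In the trophoblast list of 12 genes Krt19 and Tfap2c fell, with log2 fold changes of -2.05 and -0.60, and the list did not pass (2 adjusted over the list alone, camera adjusted p = 0.17), except without GC line 1 (0.021) and with a replicate block by full sample number without d8 line 3 (0.04). None of the 9 neuroectoderm genes changed (1 positive and 3 negative adjusted over the list alone, camera adjusted p = 0.53), with Tubb3 at 64.9 and 49.2 RPKM and Nefl at 20.7 and 25.6 RPKM in GC and d8. Of the 2-cell-like list only Arg2 was tested, at 0.937 and 1.12 RPKM (camera adjusted p = 0.53, 0 adjusted over the list alone). Without the expression filter, which admits further genes near 0, the 2-cell-like list passed as higher (camera adjusted p = 0.029).

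Clusters of genes with many CTCF sites were examined as lists as well. All 22 tested clustered protocadherins, cell adhesion genes chosen by CTCF-bound promoters, had negative values with a median log2 fold change of -0.34, and none passed singly or adjusted over the list alone (camera adjusted p = 0.021). The list had adjusted p = 0.77 with an estimated correlation and 0.12 without d8 line 1. Without GC line 1 its direction turned (camera adjusted p = 0.94). The members tested belong to the gamma cluster, whose transcripts share exons, so their values are not independent. Pcdhgc3 stood at 15.2 RPKM in GC line 1, 8.92 RPKM in GC line 2 and 6.23 to 10.4 RPKM in the d8 lines, and Pcdhgb7 at 9.76 and 7.36 RPKM in the genotype means. Of 4 Hox genes tested, Hoxd13 rose from 0.665 ± 0.0533 to 1.49 ± 0.148 RPKM (3 adjusted over the list alone, camera adjusted p = 0.023). The Hox list had adjusted p = 0.65 with an estimated correlation, 0.17 without GC line 2, 0.053 without d8 line 2, 0.12 without the expression filter and 0.061 with a replicate block by full sample number. Hoxb9, on chromosome 11, stood at 1.75 and 1.45 RPKM in GC and d8.

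Among 31 imprinted genes, 2 rose and 4 fell, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.59). Peg12 fell from 1.41 ± 0.148 to 0.127 ± 0.0345 RPKM and Peg10 from 135 ± 43.4 to 60.8 ± 7.11 RPKM. Commd1, on chromosome 11, fell from 65.0 ± 0.243 to 36.8 ± 1.28 RPKM and Magel2 from 2.85 ± 0.123 to 1.26 ± 0.352 RPKM. Of 23 genes of the DNA methylation machinery, Dnmt3a rose from 30.5 ± 1.09 to 49.3 ± 4.44 RPKM, together with Dnmt3b and Gadd45a (3 adjusted over the list alone), while the list did not pass (camera adjusted p = 0.16), except without d8 line 3 (0.024). Of 17 CTCF and cohesin genes the cohesin subunit Stag2 rose from 31.1 ± 2.92 to 42.9 ± 3.19 RPKM (1 adjusted over the list alone, camera adjusted p = 0.18). Rad21 stood at 108 and 89.7 RPKM and Cdca5 at 62.1 and 54.4 RPKM in GC and d8.

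Of 13 stress response genes, the transcription factor Atf4 rose from 218 ± 3.17 to 289 ± 20.8 RPKM (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.021). The list had adjusted p = 0.65 with an estimated correlation and 0.055 without GC line 1. Hspa5 stood at 213 and 209 RPKM and Asns at 172 and 168 RPKM in GC and d8. None of the 23 p53 targets changed (0 adjusted over the list alone, camera adjusted p = 0.5), with Bax at 276 and 343 RPKM and Ccng1, on chromosome 11, at 126 and 94.0 RPKM. Among 14 glycolysis and hypoxia genes Vegfa and Pdk1 rose, with log2 fold changes of 0.54 and 0.36 (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.74). Pdk1 missed the threshold with the line as a random block (limma adjusted p = 0.062). With a replicate block by sample letter or full sample number, Pdk1 (limma adjusted p = 0.086 and 0.073) and Vegfa (0.05 and 0.057) missed it. Of 16 proliferation genes Aurkb, Top2a and Ccnb2 fell, with log2 fold changes of -0.61, -0.46 and -0.44 (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.14, and 0.032 without the expression filter). Of 79 ribosomal protein genes Rpl27, Rpl26 and Rpl22l1 fell, with log2 fold changes of -0.58, -0.50 and -0.34 (3 adjusted over the list alone, camera adjusted p = 0.87). Rpl22l1 missed the threshold with the line as a random block (limma adjusted p = 0.065). Ribosomal protein genes have many near-identical copies, which makes their values uncertain. Aurkb, Top2a, Rpl27 and Rpl26 lie on chromosome 11, and with each chromosome centred in each line their limma adjusted p values were 0.1, 0.69, 0.34 and 0.55.

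Lines of the same genotype also differed. Between the GC lines 823 genes differed, 403 higher in line 2 and 420 higher in line 1, and among the d8 lines 289 genes differed (limma, 14 libraries). Besides Ctcf, the largest differences by p included Grb10, an imprinted growth regulator, at 28.0 RPKM in GC line 1 and 110 RPKM in GC line 2 (log2 difference 1.93, SE 0.08, limma adjusted p = 1.8e-08). Foxm1, a cell cycle transcription factor, stood at 53.2 and 23.0 RPKM (log2 difference -1.17, SE 0.07, limma adjusted p = 9.1e-07). Both were named after their values had been seen. Foxm1 lies in a stretch of chromosome 6 that stood higher in GC line 1 as a whole, described below. Many gamma protocadherins, which share exons, were also higher in GC line 1. The 823 genes are therefore not all separate differences. The GC count was 531, 354 and 484 without samples GC 1A, 2B and 2C, and the d8 count was 80, 91, 143 and 144 without samples d8 1A, 1B, 3A and 3B. In the d8 lines, samples 1A and 1B and samples 3A and 3B were the closest pairs, with a chi-square per gene of 1.33 each against 2.35 to 4.79 for the other pairs, but they differed by more than sampling noise and were kept as separate samples.

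CTCF ChIP-seq gave 26729 peaks in GC and 15546 in Del8. Of the GC peaks, 11218 (42.0%, 41.4 to 42.6) were overlapped by a Del8 peak and 15511 were not. Of the Del8 peaks, 4328 (27.8%, 27.1 to 28.5) overlapped no GC peak. The share of tags in peaks was 6.18% in GC and 4.43% in Del8. As each genotype had 1 library, and the Del8 library had fewer tags and a higher relative threshold, the shares compare these lists and not the conditions.

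Retention followed the position of a peak in the GC list, whose order was assumed to follow peak strength, as the list does not state it. It fell from 82.4% (80.9 to 83.8) in the first 10% of the list to 11.9% (10.8 to 13.2) in the last 10%. Retained peaks had a median position of 29.7% of the list and lost peaks of 64.7%. The difference was -35.0 percentage points (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). If the order follows strength, a library with fewer tags and a higher relative threshold would miss weaker peaks in any case. The test therefore cannot tell an effect of losing zinc finger 8. The 5 first retained peaks lay between genes, at 98667001 to 98667233 and 98662343 to 98662575 on chromosome 2, 35305329 to 35305561 on chromosome 9, 19417707 to 19417939 on chromosome 14 and 3109897 to 3110129 on chromosome 12. The 5 first lost peaks were at 3026549 to 3026781 on chromosome 9, between genes, at 121751507 to 121751739 and 61539903 to 61540135 on chromosome 8, within Jph3 and Palld, at 24530114 to 24530346 on chromosome 5, 3381 bp from the start site of Gbx1, and at 88553529 to 88553761 on chromosome 3, 72 bp from that of Ubqln4. The lost peak on chromosome 9 lay in a crowded stretch, between retained peaks at 3025416 to 3025648 and 3027029 to 3027261. Because no control library was named in the peak calling, whether these first peaks are CTCF sites was not tested.

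**Figure D4:**
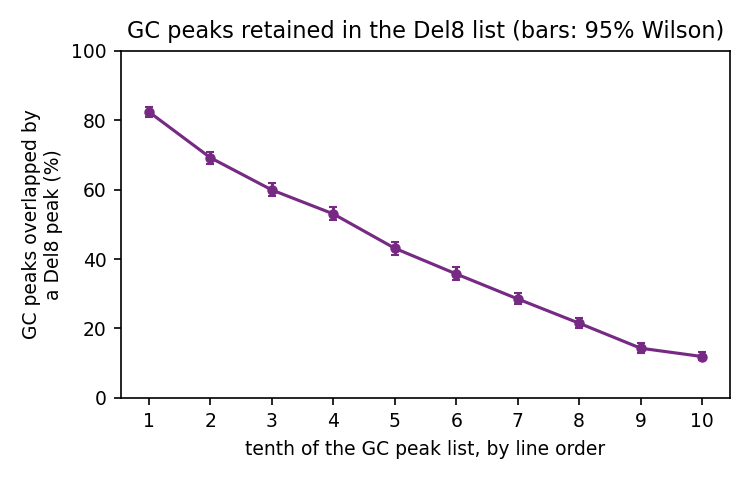
Percentage of GC peaks overlapped by a Del8 peak in 10 equal parts of the GC peak list, by position in the list, with 95% Wilson intervals. The share fell from 82.4% in the first part to 11.9% in the last.

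Peaks near promoters were retained more often. Within 1 kb of a start site 55.8% (53.8 to 57.8) of 2342 GC peaks were retained, against 40.6% (40 to 41.3) of 24387 farther away (Fisher's exact test, odds ratio 1.84, p = 4.4e-45). On the X chromosome 30.3% (26.3 to 34.6) of 465 peaks were retained, against 42.2% (41.6 to 42.8) of 26251 on the autosomes (Fisher's exact test, odds ratio 0.60, p = 2.1e-07). Within 10 equal parts of the list the odds ratio for promoters was 1.44, above 1 in 9 of the 10 parts. The X chromosome was not compared within these parts, so its lower share is not separated from list position. The clustered protocadherin region (chromosome 18, 36925285 to 37846872) held 58 GC peaks, of which 18 were retained and 40 lost. In the Hoxa, Hoxb, Hoxc and Hoxd clusters 4 of 6, 5 of 11, 3 of 3 and 3 of 7 peaks were retained, and in the X-inactivation centre 3 of 8. At Ctcf itself both GC peaks were lost, 1 of them 118 bp from the start site.

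Genes next to lost peaks did not change more often than genes next to retained peaks. Lost peaks stood lower in the GC list, at a median position of 64.7% against 29.7%. The genes were not compared within parts of the list, so the comparison does not isolate an effect of losing CTCF binding. The labels name no line for the ChIP-seq libraries, so the peaks may come from other lines than the RNA. Among genes with GC peaks within 5 kb of the start site, 160 of 1766 (9.1%, 7.8 to 10.5) near lost peaks only changed, against 226 of 1683 (13.4%, 11.9 to 15.1) near retained peaks only (Fisher's exact test, odds ratio 0.64, p = 4.9e-05). The difference lay in genes that fell, 103 (5.8%) near lost and 171 (10.2%) near retained peaks (Fisher's exact test, odds ratio 0.55, p = 2.8e-06), while 57 and 55 genes rose (odds ratio 0.99, p = 1). Of 8652 genes with no GC peak within 5 kb, 654 (7.6%, 7.0 to 8.1) changed. Chromosome 11 did not account for the difference, as the odds ratio without it was 0.61 (Fisher's exact test, p = 1.4e-04). Of the 12 lowest genes 7 had such a peak, and all of these peaks were retained at 5 of them, Col1a1, Bak1, Bola3, Got2 and Mipep. At Got2 the retained peak lay 118 bp from the start site (chromosome 8, 95888368 to 95888600). At Ocrl the GC peak 59 bp from the start site (chromosome X, 47912282 to 47912514) was lost. Among the 12 highest genes 3 had such a peak, retained at Prss50 and Trim63 and lost at Nrg2. Fisher's exact test missed the threshold at 50 kb (odds ratio 0.81, p = 0.063), without GC line 1 (0.38, p = 0.11) and without d8 line 2 (0.77, p = 0.084).

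The authors' deposited table of control against del8 cells, whose libraries match no sample of the series, lists 664 genes with positive and 616 with negative values. Of its genes, 1239 were tested here, and 1029 of them (83.1%, 80.9 to 85.0) had the same sign in d8 against GC. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.71 and rho = 0.71. Of 280 genes past the threshold here, 273 had the same sign. All 24 named genes in the authors' deposited table had the same sign. In the authors' deposited table the log2 fold change was -3.59 for Ocrl, -1.86 for Got2, -4.87 for Bak1 and -3.91 for Bola3. It was -1.01 for Nanog, 1.51 for Dnmt3a, 1.07 for Gata4 and 3.31 for Prss50 in the authors' deposited table. Chromosome 11 held 61 of the 616 negative genes of the authors' deposited table (9.9%, 7.8 to 12.5) and 41 of its 664 positive genes (6.2%, 4.6 to 8.3), against 8.6% of the genes tested here.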

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

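For the pattern on chromosome 11, the tests of lost peaks and of loss of zinc finger 8 were chosen only after the result was seen, as was the count of splits. Single samples far from the others of their genotype were sought in 154 groups of values, and 19 were found where chance gives about 7.7. Sample d8 2B supplied 5 of them, GC 2C 4 and GC 1B 3.

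In the GC libraries, fibroblast genes stood apart in single samples. Col1a1 was 28.0 RPKM in sample 2C (5.82 to 12.3 in the others) and Col1a2 11.2 RPKM in the same sample (1.53 to 3.66). Acta2 was 165 RPKM in sample 1B (36.7 to 71.8) and S100a4 8.90 RPKM in the same sample (1.20 to 3.03). Hoxb9 was also highest in 1B, at 4.99 RPKM (0.585 to 1.84). In 2C Nupr1 was highest, at 22.6 RPKM (15.2 to 17.8), and Stag2 lowest, at 24.4 RPKM (30.7 to 34.4). In 1C Cdca5 was highest, at 78.5 RPKM (55.2 to 63.7), as was Rpl26, at 331 RPKM (226 to 258).

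In the d8 libraries, sample 2B held the highest Gbx2 at 6.34 RPKM (3.30 to 4.09), Tubb3 at 71.5 RPKM (41.8 to 49.8), Acta2 at 33.1 RPKM (12.3 to 18.1) and Aurkb at 41.5 RPKM (35.2 to 38.1), and the lowest Bhlhe41 at 1.73 RPKM (3.50 to 4.92). Sample 2A held the highest Mael at 27.9 RPKM (10.8 to 18.5) and Vegfa at 13.3 RPKM (6.61 to 9.66). Sample 1C held the lowest Ctcf at 23.2 RPKM (30.8 to 37.2) and the highest Ccnb2 at 60.2 RPKM (46.7 to 49.2). In sample 1A the 10 highest genes took 4.5% of the reads (3.8 to 4.1). Without samples GC 2C and d8 2B, a choice made after seeing the data, 1252 genes passed the threshold.

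For the lower level of chromosome 11 in d8, rescaling to median ratios left the median at -0.37 (-0.39 to -0.35). As 1 factor per library moves all chromosomes alike and the others had medians between -0.13 and 0.06, this argues against library-wide scaling in the authors' normalization. Genes near lost peaks and genes with no peak differed by 0.00 (-0.04 to 0.08) on this chromosome, which argues against neighbouring lost peaks. That holds only as far as the peak lists, whose lines the labels do not name, describe the RNA-seq lines. Chromosome 11 held 9.9% (7.8 to 12.5) of the negative genes in the authors' deposited table and 52.0% (47.6 to 56.3) of the genes that fell here by 0.5 or more, which argues against loss of zinc finger 8 as the whole cause, although that table's libraries match no sample here and the bound for the test, 20%, was set with its value already seen. A difference in chromosome 11 copies between the GC and d8 lines remains a candidate explanation, since the median of 60 genes without a GC peak within 50 kb was -0.41 (-0.45 to -0.35), near that of the whole chromosome, and DNA was not examined to tell a gain in GC from a loss in d8.

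The low Ctcf level of GC line 1 was weighed as a source of the genotype difference. If it were the source, fewer than 60% of the genes of the authors' deposited table should have the same sign without that line. Instead 83.5% (81.4 to 85.5) had it. That share covers only the genes of that table. Among them were 273 changed genes of the same sign and 7 of the other, so the share does not decide for the remaining changed genes. The number of changed genes fell to 27 without GC line 1, and that comparison has 1 GC line left. What lowers Ctcf in GC line 1 was not tested, and loss of zinc finger 8 stays open as a biological explanation of the genes that changed.

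Lower fibroblast genes in d8 may come from RNA of feeder cells or fibroblasts in the GC libraries or from a difference among the ES cells, and these cannot be told apart. Such RNA would bring all abundant fibroblast transcripts, and of Col3a1, Postn, Dcn and Lum only Lum stood below 10% of Col1a1 in GC line 1, while Postn, Dcn and Lum did in GC line 2, so that 1 of the 4 did in both. Col3a1 was 4.46 and 1.87 RPKM in the GC lines against 0.32 to 0.95 RPKM in d8, and Postn 1.03 and 1.31 against 0.021 to 0.11 RPKM. Dcn, at 2.29 and 0.38 RPKM in the GC lines and 0.64 to 1.37 RPKM in d8, did not follow them. The labels do not state whether feeder cells were used.

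The 5 lines can be divided into 2 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1092 genes, and the highest of the others gave 0; only the real division, 1 of the 10, reached that number.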

How the results depend on the processing

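Against 1092 changed genes (376 higher, 716 lower), the planned settings gave 290 without an expression filter, 2545 with the line as a random block, 4029 with 14 independent libraries and 150 at an absolute log2 fold change of at least 1. Leaving out GC lines 1 and 2 gave 27 and 511 genes, leaving out d8 lines 1, 2 and 3 gave 117, 579 and 30, and single libraries 745 to 1451. The cause of the changes was not tested, but fewer lines leave less information, and independent libraries treat samples of a line as separate lines. Chosen after seeing the data, 368 genes (188 higher, 180 lower) passed without chromosome 11, 489 (260 and 229) with chromosomes centred per line, and 7 without chromosome 11 and GC line 1. With voom on recovered reads 1234 genes passed (522 and 712). The 1092 genes kept their direction under every alternative that tested them except centring, where 1069 did. As they were chosen from the same libraries, this is no independent support.

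With a replicate block the count was 2230 by sample letter and 2932 by full sample number without d8 line 3, where the lists passing numbered 8 and 9 and 83% and 80.8% of genes had the sign of the authors' deposited table. With this replicate block Dnmt3b had adjusted p = 0.13 and 0.093, Pdk1 0.086 and 0.073, and the formative list 0.18 and 0.12. By letter Otx2 (0.069), S100a4 (0.059), Rpl22l1 (0.083), Vegfa (0.05) and general pluripotency (0.062) also missed the threshold, and by full number Vegfa (0.057) and the Hox list (0.061). Ctcf passed by both (0.042 and 0.033), and Tubb3 (0.03), Rad21 (0.045), Ccng1 (0.048) and the trophoblast list (0.04) by full number. The correlation of samples of the same number lay between -0.2 and 0.08 for deviations from the genotype mean and between -0.16 and 0.31 for deviations from the line mean, the highest for 2A. Of 6 GC samples only 1C and 2A had their own number as the closest d8 partner.

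Of 21 lists 10 passed, 6 without GC line 1, without d8 line 1, without d8 line 2 and with voom, 0 with an estimated correlation and 1 with fry (range without a line 6 to 11). Rescaling left 7, with general pluripotency, formative and germline genes at an adjusted p of 0.052. Without the filter the formative (0.064), germline (0.11), mesoderm (0.064) and Hox (0.12) lists missed the threshold and the 2-cell-like (0.029) and proliferation (0.032) lists passed. The cause was not tested. The protocadherin list turned to higher without GC line 1 (adjusted p = 0.94). Of 74 named genes 48 were weaker without GC line 1 and 48 without d8 line 3, and no gene past the threshold changed direction. Among the genes not past it, T turned from -1.26 to 0.24 without GC line 1. Hoxb9, at -0.03, was 0.37 without GC line 1 and with chromosomes centred per line, 0.20 without sample GC 1B, 0.08 without d8 line 1 and 0.05 at a pseudocount of 0.1. Hspa5, Asns and Snai1, all near 0, also changed sign. Differences between GC lines numbered 354 to 1054 and between d8 lines 80 to 404 when single libraries were left out.

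The retained share of GC peaks, 42.0%, was 39.7% at a reciprocal overlap of 50% and 38.7% with centres within 100 bp, as both are stricter. By list position it was 61.5% in the upper 50%, 22.4% in the lower 50% and 57.9% among the first 15546 peaks; the position difference was -35.5 with reciprocal overlap. The odds ratio of changed genes near lost against retained peaks, 0.64, missed the threshold at 50 kb (0.81), without GC line 1 (0.38) and without d8 line 2 (0.77), and without single lines ranged from 0.20 to 0.77. The share of genes with the sign of the authors' deposited table, 83.1%, was 85.6% without samples GC 2C and d8 2B and 77.6% to 84.4% with a line or library left out. The cause was not tested. The CTCF motif was not run, and neither was the filter on peak score. Depth limits low genes, since 1 RPKM stands near the filter, and the Del8 library had 5.59 M tags against 8.09 M in GC.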

Other observations

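All values in this part were picked after the results were seen, and none had a test planned beforehand.

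Regions of single lines stood apart in expression beyond chromosome 11. In GC line 1 a stretch of chromosome 6 from 120.9 to 137.8 Mb, with 64 genes, lay 0.51 above the other lines in the median of running medians on the log2 scale, and up to 0.96. It contains Foxm1 and Tulp3, and Tulp3, which acts in cilia, stood at 58.6 RPKM in GC line 1, 20.7 RPKM in GC line 2 and 23.8 RPKM in the d8 mean. In GC line 2 a stretch of chromosome 16 from 45.2 to 91.7 Mb, with 57 genes, lay 0.46 above the others, and a stretch from 32.2 to 43.9 Mb, with 41 genes, 0.40 above. In d8 line 1 a stretch of chromosome X from 56.6 to 96.0 Mb, with 63 genes, lay 0.73 above the others. The median of chromosome 19 was 0.24 higher in GC line 1 than in the other lines.

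On chromosome 18 a run of 27 genes from 37.0 to 37.9 Mb lay 0.61 above the other lines in GC line 1. In d8 line 1 a run of 26 genes there lay -0.47 from the other lines. The clustered protocadherins tested there belong to the gamma cluster and share exons. Their values are not independent, so these runs do not show a shift of the whole protocadherin region. The gamma cluster gene Pcdhgc3 differed between the GC lines, at 15.2 RPKM in line 1 and 8.92 RPKM in line 2 (log2 difference -0.71, SE 0.13, limma adjusted p = 0.0088).

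Single genes picked from the differences between the GC lines follow. Rhox5, a homeobox gene of the X chromosome, stood at 23.5 RPKM in GC line 1, 144 RPKM in GC line 2 and 119 RPKM in the d8 mean (log2 difference 2.44, limma adjusted p = 2.7e-04). Dppa4, a pluripotency gene, stood at 30.7, 64.0 and 51.6 RPKM. Bak1 was higher in GC line 2 than in GC line 1 (log2 difference 1.82, limma adjusted p = 6.3e-05), while both lay above the d8 mean of 0.445 RPKM.

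Peaks of the Del8 list without a GC counterpart were most frequent on chromosome 8, where 510 of 1255 Del8 peaks (40.6%, 38.0 to 43.4) overlapped no GC peak, against 26.7% (26.0 to 27.4) of 14291 on the other chromosomes. Of the Del8 peaks without a GC peak, 6.7% lay within 1 kb of a start site, against 8.8% of all GC peaks. The first of them in the list lay 216 bp from the start site of B3glct (chromosome 5, 149678351 to 149678597) and the next 176 bp from that of Zbtb45 (chromosome 7, 13009554 to 13009800).

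The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were listed at 0 in all 14 libraries, Uty was above 0 in 1 library, at 0.013 RPKM, and Xist reached at most 1.81 RPKM.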
